A study of Mus musculus with 16 samples.

How the data were processed

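Total RNA from livers of 16 male C57BL/6 mice, 3 months old per the labels, was labelled with Cy3 and hybridised singly to Agilent whole mouse genome arrays. The 4 groups of 4 arrays were wild type and liver GR knockout, each untreated or given dexamethasone. Genotype and treatment were taken from the source names and characteristics. Titles of the knockout samples also carry the word PBS, and the protocol speaks of vehicle where the sources say no treatment. The dose, route and duration of dexamethasone and the deleted part of the gene are not given in the sources used here. The labels do not say outright that each replicate was a separate mouse, which was assumed.

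The deposited scanner files hold the processed signal of each spot as an intensity, background-subtracted and detrended within the array, which the authors extracted with Agilent Feature Extraction 9.5 per the submitters' processing notes. Raw mean and local background signals are an intensity as well, per the file headers. The flags for signal above background, saturation and outlying spots are of the kind other, per the file headers. The deposited series table is also an intensity, and its largest difference from the processed signal was 0. No normalization between arrays had been applied. Each array carries 45018 spots, of which 1639 are controls, and 41174 probes for transcripts. Probe positions are on the mm7 build as the deposited annotation gives them, and current gene symbols were matched through RefSeq accessions for 22951 probes and through symbols or synonyms for 9811, while 8412 had an accession or clone only.

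Control spots were left out, 2121 outlying spots (0.31%) were set to missing, and spots of 1 probe were averaged. The log2 signal was centred on each array's 75th percentile. Probes well above background on at least 3 of the 4 arrays of any group were kept (26792), and the probe with the highest mean stood for each gene, which left 19055 genes, 15747 with a symbol. Limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 16 arrays (12 residual degrees of freedom). The 5 comparisons were dexamethasone in each genotype, their difference (the interaction), and knockout against wild type with and without dexamethasone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison, and all tests were two-sided. Where a group was above background on none of its arrays, the fold is given as a lower bound, and a fitted interaction is not read as a size.

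In the tests of gene lists, 21 lists and 12 sets of cell type markers were tested with camera at a correlation of 0.01 over 19031 genes with no missing array, adjusted over the 33 of each comparison. Estimated correlation and fry, which tests whether the genes of a list move 1 way on balance, were alternatives. Levels in the text are log2 values relative to the array's 75th percentile. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

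The comparisons, tests, lists, most alternatives and the rule for naming genes were set before the data were examined. The rule took Nr3c1, the 8 largest rises and 8 largest falls among called genes with a symbol, signal above background on every array of a group compared and no overlap between the arrays of the sides (an overlap rule not used for the interaction), up to 4 called members of each called list, and up to 2 of other lists described. It named 254 results, of which 72 lost their call when some 1 array was left out. The genes printed were picked from these after their values were seen, mostly those whose call held (6 of the 128 called ones did not hold), so they look steadier than the 254 as a whole. A gene that the rule named is not reported here. Outlying arrays were looked for in the printed genes and lists only.

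Each slide held 1 group only, so slide could not be fitted as a block. Replicate numbers were not taken to pair the samples, so no pairing entered the main fit. Correlations of residuals between groups by number lay between -0.192 and 0.341 with a median of 0.0755. Of 24 pairs, 10 passed 0.1, the size set for pairing, and 12 correlated best with their own number. Some pairing is therefore not excluded. The number was also the position of the array on its slide. On simulated data with 200 of 19055 genes changed, over 5 draws, genes with a log2 change of 1 were recovered at 54%, 60%, 27.2%, 54% and 50.8% for dexamethasone in wild type, in knockout, the interaction, and knockout without and with dexamethasone, and those with a change of 2 at 89.2%, 88.8%, 73.2%, 86.8% and 88.4%. Alternatives were normexp background correction (offset 50), quantile normalization, a percentile over bright probes, no filter and a stricter filter on dim probes, outlying spots kept, other ways to join probes, a trended robust variance, array weights, replicate as a block, the series table, only the groups compared, a threshold of 2-fold, and each array left out in turn. Leaving out untreated knockout array 1 together with untreated wild-type array 4, the dimmest, was chosen after seeing the data, as was treating array 1 as standing apart.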

Results

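Gene expression was measured in livers of male C57BL/6 mice, 3 months old, on 16 Agilent whole mouse genome arrays, 1 RNA sample per array. The 4 groups held 4 arrays each: wild type without treatment, wild type given dexamethasone, GR knockout without treatment and GR knockout given dexamethasone. Dexamethasone is a synthetic glucocorticoid, and GR is the glucocorticoid receptor, encoded by Nr3c1 and deleted in liver in the knockout. The 75th percentile of the signal lay between 523.9 and 691.1 on 14 arrays, and was 400 on untreated wild-type array 4 and 309 on untreated knockout array 1. Between 57.3% and 67.9% of spots were well above background. Untreated knockout array 1 correlated less with its group (mean r 0.963 across genes) than the other 3 did (0.975 to 0.980), and it lay at -85 on the first principal component. Each slide held the 4 arrays of 1 group, so slide and group cannot be told apart in any comparison. The number of arrays limits the precision of each value.

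The first comparison asked how much Nr3c1 transcript the knockout livers kept. Nr3c1, on chromosome 18 of the mm7 build, fell by 1.99 on the log2 scale without dexamethasone (SE 0.15, n = 4 per group, 3.96-fold, adjusted p = 1.8e-05) and by 1.96 with it (SE 0.15, 3.9-fold, adjusted p = 6.5e-06). These values came from probe A_52_P138090, at 39787242 to 39787301. Probe A_52_P63106, at 39789494 to 39789553, fell by 2.10 without and by 1.95 with dexamethasone (SE 0.18 each). Probe A_51_P355693 was lower as well, but it was above background on 0 of 4 untreated and 1 of 4 treated knockout arrays, so the size of its fall is not given. Probe A_52_P254174 was not called in either comparison (-1.62, adjusted p = 0.10, and -0.97, adjusted p = 0.20, SE 0.51). Without treated knockout array 1, which was at -1.46, its difference under dexamethasone was -1.68 and was called (adjusted p = 8e-04). Dexamethasone did not change Nr3c1 past the threshold in wild type (-0.27, SE 0.15) or in knockout (-0.25, SE 0.15). The position of the deletion within the gene is not given in the sources used here, so whether these probes lie inside it is unknown.

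**Figure D1:**
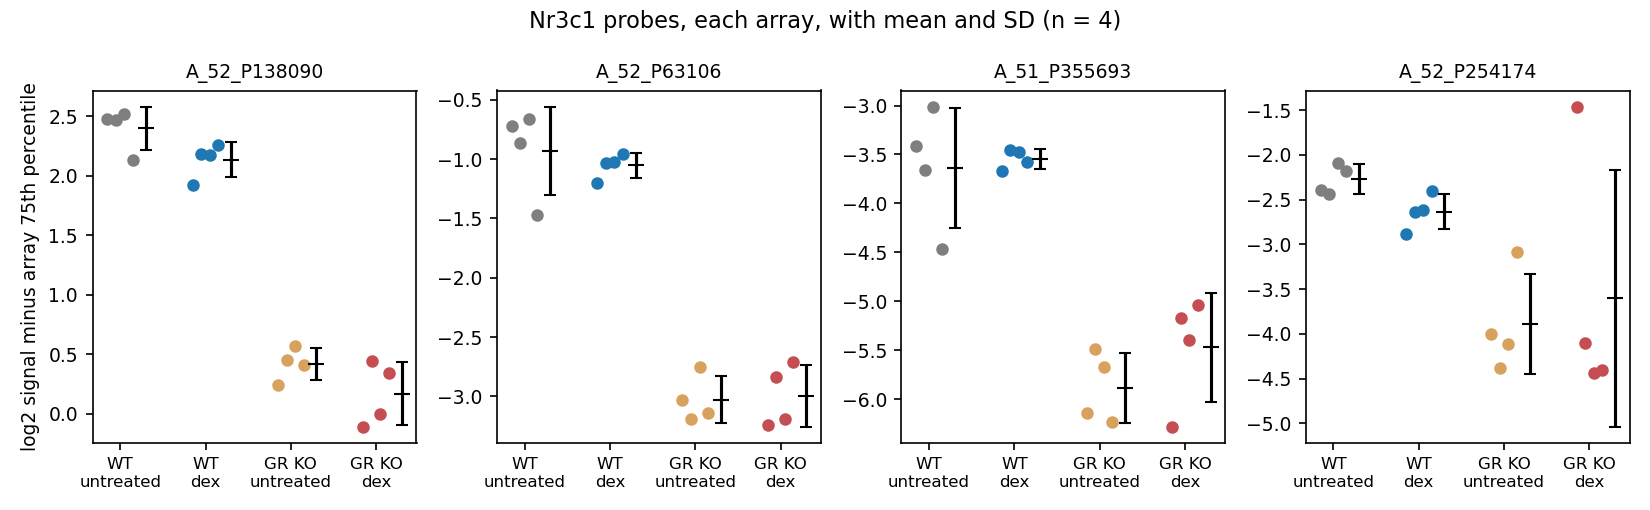
Level of 4 Nr3c1 probes on each of the 16 arrays (log2 signal minus the array's 75th percentile), with the mean and SD of each group. In probe A_52_P138090 the group means were 2.40 and 2.13 in wild type and 0.42 and 0.17 in knockout.

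The comparison of treated with untreated wild-type livers asked which genes dexamethasone changes where the receptor is present. The steroid sulfotransferase Sult1e1 rose 76.8-fold (log2 6.26, SE 0.75, n = 4 per group), the iron-binding acute phase protein Lcn2 86.5-fold (log2 6.44, SE 0.93) and the cell cycle inhibitor Cdkn1a 54.6-fold (log2 5.77, SE 0.81). Gadd45b, a stress-response signalling gene, rose 51.3-fold (log2 5.68, SE 0.57), and Fam107a, an actin-binding protein gene, rose as well (log2 8.49, SE 1.21). Fam107a was above background on 1 of 4 untreated arrays, so the size of its rise rests on the floor (5.65 under normexp background correction). Untreated array 4 lay toward the treated arrays for each of these genes, least for Gadd45b (-0.59, against -2.05 to -1.53 on the other untreated arrays). Without it the changes were 7.58 for Lcn2, 7.10 for Sult1e1, 6.71 for Cdkn1a and 10.12 for Fam107a. Leaving out 1 other untreated array gave 5.73 for Lcn2, 5.65 for Sult1e1 and 7.72 for Fam107a without array 3, and 5.17 for Cdkn1a without array 2. Thyroglobulin, Tg, was below background in untreated livers and rose at least 24-fold. Among the falls, Ppp1r3g, a regulator of glycogen synthesis, decreased 16.5-fold (log2 -4.04, SE 0.71) and the clock output gene Dbp 6.69-fold (log2 -2.74, SE 0.27). Srebf1, which drives fatty acid synthesis, fell by 2.57 (SE 0.52), with untreated array 4 at 5.12 against 6.23 to 7.81 on the other untreated arrays. The membrane protein gene Tspan18 fell by 3.02 (SE 0.44, and -1.52 under an alternative), while the clock gene Arntl rose by 2.48 (SE 0.53). The keratin Krt23 fell by 2.69 (SE 0.48), the chemokine gene Cxcl10 by 2.63 (SE 0.46), the endothelial receptor gene Kdr by 1.13 (SE 0.24) and the sterol exporter Abcg5 by 0.94 (SE 0.21). Limma called 2277 of 19055 genes at an adjusted p under 0.05, 983 higher and 1294 lower. The count was 1240 without untreated array 2 and 1270 without treated array 1.

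**Figure D2:**
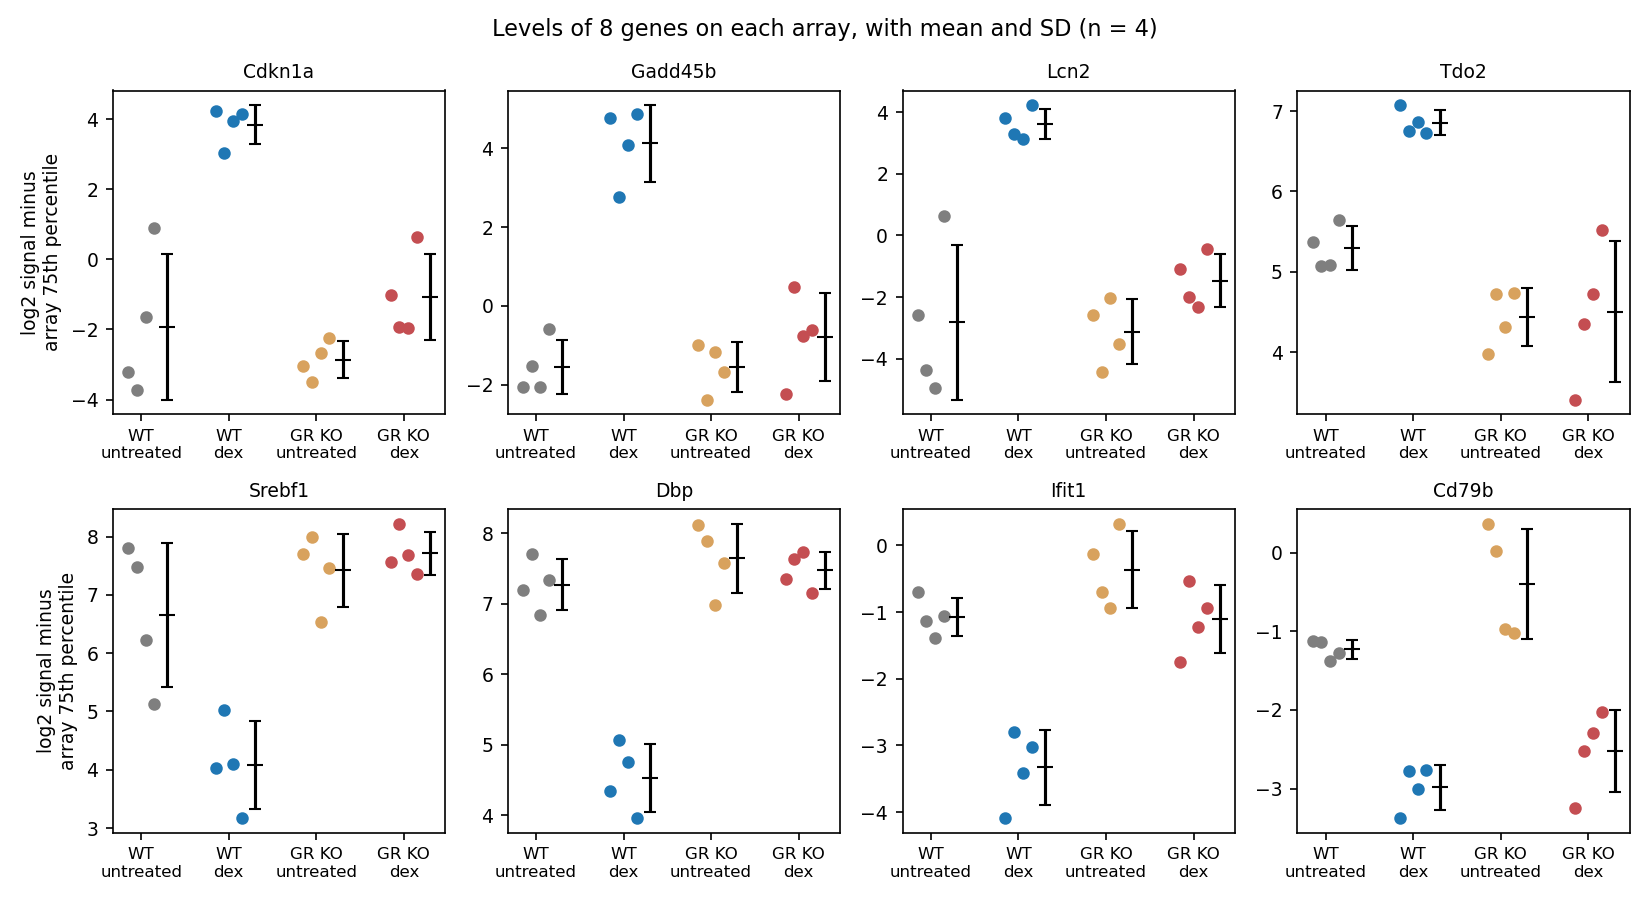
Levels of Cdkn1a, Gadd45b, Lcn2, Tdo2, Srebf1, Dbp, Ifit1 and Cd79b on each of the 16 arrays (log2 signal minus the array's 75th percentile), with the mean and SD of each group of 4. Gadd45b rose by 5.68 with dexamethasone in wild type, and its response was smaller by 4.92 in knockout.

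Of the gene lists set against all other genes with camera, 8 were called in wild-type liver, and none of the 8 was called with an estimated correlation. The classic glucocorticoid-induced genes rose (10 of 19 called higher, 11 adjusted over the list alone, adjusted p = 5.32e-08, adjusted p = 0.364 with an estimated correlation), including the metallothioneins Mt1 (log2 4.59, SE 1.01) and Mt2 (log2 4.90, SE 1.15) and the mTOR inhibitor Ddit4 (log2 3.38, SE 0.49). Untreated array 4 was at 8.10 for Mt1 and 8.80 for Mt2, close to the treated arrays, and without it their changes were 5.95 and 6.42, against 3.90 and 4.00 without untreated array 1. The acute phase list rose (9 of 25 called, 10 adjusted over the list alone, adjusted p = 2.02e-05, adjusted p = 0.364 with an estimated correlation), with the serum amyloids Saa1 (log2 3.26, SE 0.63) and Saa3 (log2 3.51, SE 0.57). Untreated array 4 was at 7.11 for Saa1 and 4.53 for Saa3, against 4.26 to 5.68 and 1.96 to 3.17 on the other untreated arrays. No list was refitted without that array. The urea cycle list rose (2 of 8 called, 3 adjusted over the list alone, adjusted p = 0.00491, adjusted p = 0.588 with an estimated correlation), with the ornithine carrier Slc25a15 up by 1.63 (SE 0.22). Amino acid catabolism rose (5 of 22, 6 adjusted over the list alone, adjusted p = 0.0222, adjusted p = 0.728 with an estimated correlation), with Tdo2 (log2 1.56, SE 0.33), Aass (log2 1.47, SE 0.22) and Sdsl (log2 1.32, SE 0.23) for tryptophan, lysine and serine. Female-biased liver genes rose (5 of 14, 6 adjusted over the list alone, adjusted p = 0.00196, adjusted p = 0.588 with an estimated correlation), among them the oxygenase Cyp2b9 (log2 3.77, SE 0.86), and the related Cyp2b10 rose by 4.21 (SE 0.83).

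Interferon-stimulated genes fell in treated wild-type liver (13 of 24 called lower and 2 higher, against 18 lower and 2 higher adjusted over the list alone, adjusted p = 6.53e-08, adjusted p = 0.364 with an estimated correlation). The antiviral genes Ifit1 (log2 -2.26, SE 0.33), Ifit3 (log2 -1.75, SE 0.26) and Rsad2 (log2 -1.54, SE 0.30) fell, and Usp18, a brake on interferon signalling, rose (log2 1.47, SE 0.24). B cell markers fell (5 of 11, 6 adjusted over the list alone, adjusted p = 0.00326, adjusted p = 0.364 with an estimated correlation). The antigen receptor subunit Cd79b fell by 1.75 (SE 0.31), the IgM receptor gene Fcmr fell at least 4.47-fold and the surface antigen gene Ms4a1 at least 2.62-fold, both below background after treatment and neither called under normexp. Cholesterol synthesis fell (6 of 24 called lower, against 7 lower and 1 higher adjusted over the list alone, adjusted p = 0.0222, adjusted p = 0.728 with an estimated correlation), with the sterol carrier Stard4 down by 2.05 (log2 -2.05, SE 0.28). Untreated array 4 was at 2.63 for Stard4, against 3.75 to 4.10 on the other untreated arrays. The circadian list was not called (adjusted p = 0.969, 4 of 18 members higher and 2 lower). At an unadjusted p under 0.05 in limma, 4 members were higher and 7 lower. Camera tests for a shift 1 way, so the missing list call does not speak against a change in members that moved both ways.

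**Figure D3:**
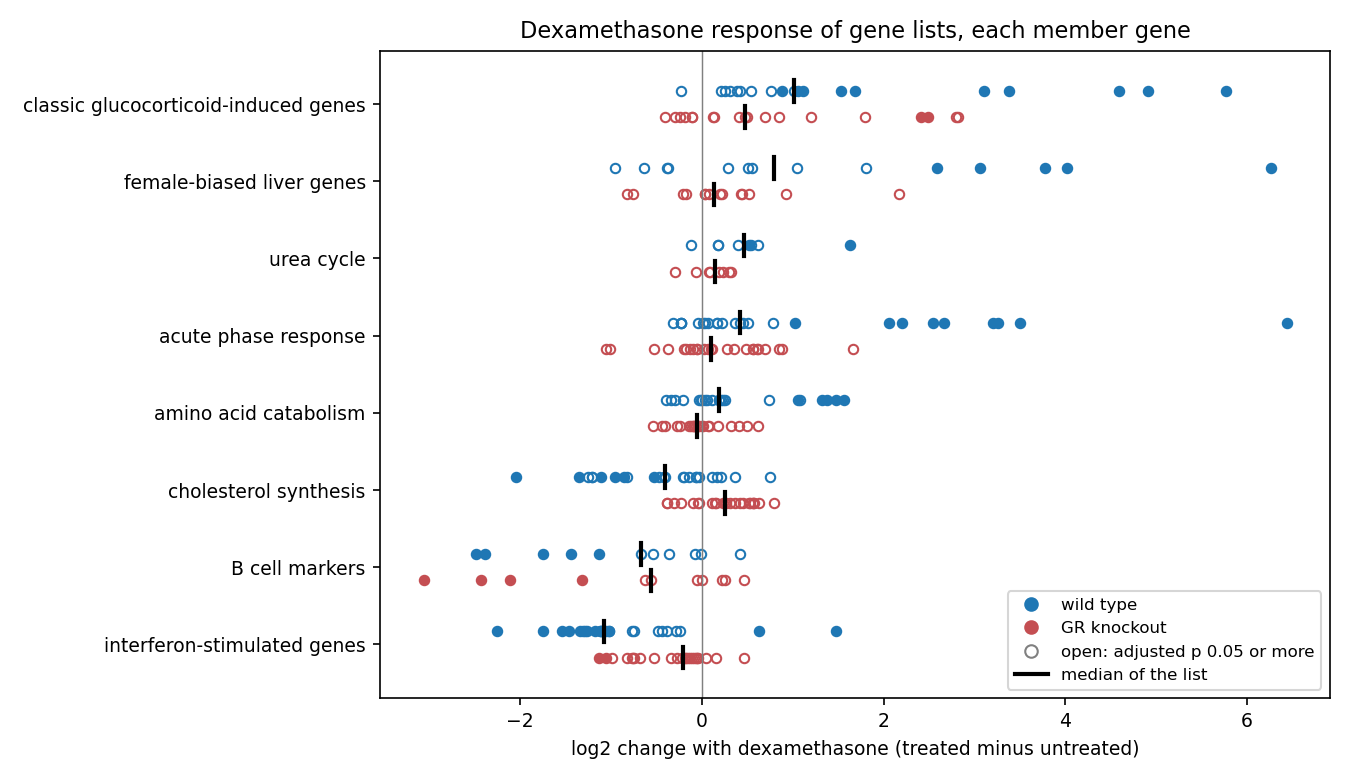
Log2 change with dexamethasone of each member of the 8 lists called in wild-type liver, in wild type and in knockout (n = 4 arrays per group), with filled points for an adjusted p under 0.05 and a bar at the median. The interferon-stimulated list had a median of -1.08 in wild type and -0.20 in knockout, and the B cell list -0.67 and -0.56, the latter 0.09 under normexp background correction.

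The same comparison in GR knockout livers asked which responses remain without the hepatic receptor. The growth regulator Ccn2 rose 7.48-fold (log2 2.90, SE 0.40, n = 4 per group), the endothelial hyaluronan receptor Lyve1 5.96-fold (log2 2.58, SE 0.33) and the adhesion molecule Vcam1 4.61-fold (log2 2.20, SE 0.33). Lyve1 (log2 2.41, SE 0.33) and Vcam1 (log2 1.46, SE 0.33) also rose in wild type. Ddit4 rose by 2.49 (SE 0.49) in knockout, and the receptor chaperone gene Fkbp5 by 2.42 (SE 0.61, adjusted p = 0.043). The call of Fkbp5 was lost without 7 of the 8 arrays in turn, and without treated array 4 its change was 1.94 (adjusted p = 0.12). Tspan18 fell by 3.15 (SE 0.44, and -1.64 under an alternative), the creatine synthesis gene Gatm by 2.58 (SE 0.43) and the class II transactivator Ciita by 1.94 (SE 0.25). The actin regulator Enah rose at least 1.55-fold, and the olfactory receptor genes Olfr1371 and Olfr1471 at least 2.36-fold and 1.41-fold, each from below background, and Enah was -0.54 with no filter on dim probes, which takes another of its probes. Under normexp Ddit4 (2.36), Gatm (-1.56), Ciita (-0.55), Fkbp5, Enah, Olfr1371 and Olfr1471 lost their call, as did Fkbp5 and Gatm with only the groups compared in the fit and Fkbp5 and Olfr1471 with no filter on dim probes. Limma called 677 genes, 222 higher and 455 lower. The count was 420 without untreated array 2, 397, 320 and 412 without treated arrays 2, 3 and 4, and 941, with 595 higher and 346 lower, without untreated array 1.

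In treated knockout liver 4 lists were called by camera, each with an adjusted p = 0.783 with an estimated correlation. B cell markers fell (4 of 11 called, 4 adjusted over the list alone, adjusted p = 0.00897), and T and NK cell markers fell (2 of 16, 4 adjusted over the list alone, adjusted p = 0.00897), although both lists lost their call and had positive medians under normexp background correction (0.09 and 0.05). Ms4a1, above background on 1 of 4 treated arrays, fell by 3.06 (SE 0.53, n = 4 per group), Fcmr by 2.43 (SE 0.32), Cd79b by 2.12 (SE 0.31) and the T cell receptor subunit Cd3e by 0.93 (SE 0.13). Interferon-stimulated genes fell (2 of 24, 4 adjusted over the list alone, adjusted p = 0.00885), with the antiviral genes Oasl2 down by 1.13 (log2 -1.13, SE 0.20) and Ifit2 by 1.06 (log2 -1.06, SE 0.18). Under normexp Ms4a1 (-0.58), Fcmr (-0.72), Oasl2 (-0.73) and Ifit2 (-0.15) lost their call, as did Ms4a1 and Cd79b with only the groups compared in the fit. Classic glucocorticoid-induced genes rose (2 of 19, 4 adjusted over the list alone, adjusted p = 0.0122). This list was not called under normexp, where of the 4 lists the interferon one kept its call. Without untreated knockout array 1 the B cell, T and NK cell and classic lists were each at an adjusted p = 0.0766, the interferon list kept its call (median -0.34, adjusted p = 0.0111) and fatty acid oxidation was called lower (median -0.24, adjusted p = 0.0111).

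A test of the interaction asked which genes responded differently in the 2 genotypes. Gadd45b responded less in knockout by 4.92 on the log2 scale (log2 -4.92, SE 0.80, n = 4 per group), and so did the antimicrobial peptide gene Defb1 (log2 -4.68, SE 0.72), Usp18 (log2 -1.75, SE 0.34) and the lysine-degrading Aass (log2 -1.46, SE 0.31). Cd3e, which fell with dexamethasone in knockout and was not called in wild type, had an interaction of -1.10 (SE 0.18). Dbp, which fell in wild type, had an interaction of 2.57 (SE 0.39). The mineralocorticoid receptor Nr3c2 (log2 1.66, SE 0.37), the bile acid regulator Fgfr4 (log2 0.99, SE 0.21) and the chaperone Hspa1l (log2 3.44, SE 0.69) also differed, although Hspa1l was above background on 1 of 4 arrays in 2 groups. Tg and Olfr1371 passed as well, and as each was above background on 0 of 4 arrays in 1 or 2 groups, no size is given. Under normexp Tg, Olfr1371, Nr3c2 (0.95), Hspa1l (1.51) and Fgfr4 lost their call, as did Slc25a15, Stard4 and Srebf1, which are given next and which lost it with no filter on dim probes, as did Sult1e1. Sult1e1 (log2 -4.09, SE 1.07), the acute phase gene Orm3 (log2 -3.72, SE 0.86), Slc25a15 (log2 -1.33, SE 0.32), Stard4 (log2 1.66, SE 0.39) and Srebf1 (log2 2.86, SE 0.74) passed. These 5 lost their call without 13, 4, 6, 7 and 12 of the 16 arrays in turn, with adjusted p = 0.091, 0.056, 0.062, 0.061 and 0.09 without untreated wild-type array 2, and Sult1e1 was at -3.48 and -4.93 without untreated wild-type arrays 3 and 4. Limma called 867 genes, 359 positive and 508 negative. The count was 506 without untreated wild-type array 2, 572 without treated wild-type array 3, 571 and 522 without treated knockout arrays 2 and 3, and 1526, with 870 positive, without untreated knockout array 1.

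Camera called 10 lists for the interaction, each with an adjusted p = 0.804 with an estimated correlation. The classic glucocorticoid-induced list was lower in knockout response (median -0.65, adjusted p = 0.00358), although limma called 0 of its 19 members over all genes and 0 adjusted over the list alone, against 3 at an unadjusted p under 0.05. Acute phase genes were lower (2 of 25, 5 adjusted over the list alone, adjusted p = 0.00358), with Orm3 among them, and cholesterol synthesis was higher (3 of 24, 4 adjusted over the list alone, adjusted p = 0.00358), with Stard4. Interferon-stimulated genes were higher (2 of 24 positive and 1 negative, against 3 and 1 adjusted over the list alone, adjusted p = 0.0123). Lists for amino acid catabolism (1 of 22, 1 adjusted over the list alone, adjusted p = 0.0267) and urea cycle (1 of 8, 1 adjusted over the list alone, adjusted p = 0.0424) were lower, as were female-biased genes (2 of 14, 4 adjusted over the list alone, adjusted p = 0.0346) and stellate cell markers (0 of 13, 0 adjusted over the list alone and 1 unadjusted in limma, adjusted p = 0.0424). Lipogenesis (2 of 20, 3 adjusted over the list alone) and glucocorticoid handling (1 of 10, 3 adjusted over the list alone) were higher, each at adjusted p = 0.0346, with Srebf1 and Nr3c2. Without untreated knockout array 1 the cholesterol, lipogenesis, glucocorticoid handling and stellate lists lost their call, and 6 lists kept it. Under normexp the lipogenesis and glucocorticoid handling lists lost theirs.

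The 2277 genes called in wild-type liver were followed into the knockout. Of these, 452 passed the interaction, and 415 of the 867 genes that passed it were not called in wild type. Choosing genes by their wild-type change inflates that change, which favours a smaller response in knockout by comparison. This bears on the 452 and on the medians set side by side below. The responses share no arrays, so the choice does not itself shrink the knockout changes. In knockout 181 passed in the same direction, 66 higher and 115 lower, where independence would give 11.5 and 30.9. Another 81 passed in the opposite direction, for which no number under independence was computed. Both responses were tested with the same estimate of spread per gene, which can raise the overlap in either direction. The excess of same-direction genes alone therefore does not show a shared response. Lyve1, Vcam1 and Ddit4 were among the 66, and Tspan18, Cd79b, Fcmr and Ms4a1 among the 115. The median change in the wild-type direction was 0.87 in wild type and 0.19 in knockout (SD 0.043 over the 4 treated knockout arrays), and 75.1% of the genes moved the wild-type way. Across all genes, which are not independent replicates, the 2 responses correlated with r = 0.138 and rho = 0.213. The number passing the interaction was 290 and 203 without untreated wild-type arrays 1 and 2, 239, 287 and 287 without treated wild-type arrays 1, 3 and 4, 861 without untreated knockout array 1 and 280 without treated knockout array 3. The number passing the same way was 117 without treated wild-type array 1 and 100 without treated knockout array 3, and the median in knockout was 0.117 without untreated knockout array 1.

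**Figure D4:**
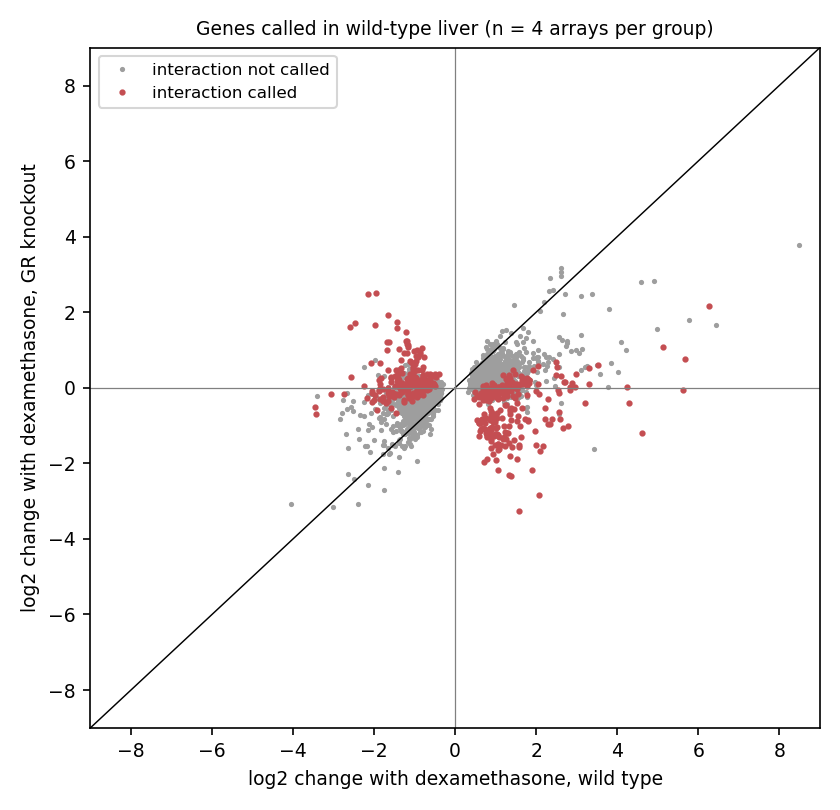
Log2 change with dexamethasone in wild-type (x axis) and GR knockout liver (y axis) of the 2277 genes called in wild type (n = 4 arrays per group), with the 452 genes that passed the interaction in red and the line of equal response. The median change in the wild-type direction was 0.87 on the x axis and 0.19 on the y axis.

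Untreated knockout livers were compared with untreated wild-type livers, which asked what loss of the receptor changes without added hormone. Lpin1, a phosphatidate phosphatase, fell 10.4-fold (log2 -3.38, SE 0.39, n = 4 per group), Fkbp5 9.54-fold (log2 -3.25, SE 0.61) and the ferritin receptor gene Scara5 13.3-fold (log2 -3.73, SE 0.68). The transcription factor Cebpd fell by 1.94 (SE 0.29), the clock gene Per1 by 1.90 (SE 0.23) and the lipase inhibitor Angptl4 by 1.29 (SE 0.22). Cfd, which encodes complement factor D, rose 60.9-fold (log2 5.93, SE 0.88). The organic anion transporter Slc22a26 rose by 3.09 (SE 0.42, and 1.75 under an alternative) and Kbtbd11, a Kelch-domain gene, by 2.84 (SE 0.40). The pancreatic elastase gene Cela3b rose too, and it was above background on 1 of 4 wild-type arrays, so its change of 2.44 (SE 0.31) rests on the floor. Tnf, an inflammatory cytokine, and the trypsinogen Prss2 rose at least 1.32-fold and 1.61-fold from below background. Under normexp Cela3b (0.74), Scara5 (-2.09), Tnf and Prss2 lost their call, and with only the groups compared in the fit Fkbp5, Angptl4, Scara5, Tnf and Prss2 lost it. Without wild-type array 4 the changes of Fkbp5 and Scara5 were -2.66 and -3.04. Limma called 543 genes, 395 higher and 148 lower. The count was 354, 162 and 298 without wild-type arrays 1, 2 and 3 and 306 and 343 without knockout arrays 2 and 4, and without knockout array 1 it was 455, with 232 higher and 223 lower.

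Camera called 18 lists in untreated knockout liver, and none with an estimated correlation. Classic glucocorticoid-induced genes fell (7 of 19, 11 adjusted over the list alone, adjusted p = 6.01e-12, adjusted p = 0.161 with an estimated correlation), with Fkbp5, Lpin1, Cebpd and Per1. Gluconeogenesis fell (2 of 12, 2 adjusted over the list alone, adjusted p = 6.28e-05, adjusted p = 0.344 with an estimated correlation), with the glucose-6-phosphatase gene G6pc down by 1.30 (log2 -1.30, SE 0.22, n = 4 per group). The urea cycle fell (2 of 8, 4 adjusted over the list alone, adjusted p = 0.000166, adjusted p = 0.344 with an estimated correlation), with the arginase Arg1 down by 0.98 (log2 -0.98, SE 0.16), not called with only the groups compared in the fit. Amino acid catabolism fell (0 of 22 in limma, 2 adjusted over the list alone, 6 unadjusted, adjusted p = 3.13e-05, adjusted p = 0.382 with an estimated correlation). B cell markers rose (2 of 11, 5 adjusted over the list alone, adjusted p = 0.000784, adjusted p = 0.344 with an estimated correlation), with immunoglobulin mu, Igh-6 (log2 1.53, SE 0.24), and the B cell factor Pax5, at least 1.12-fold from below background and not called under normexp. Interferon-stimulated genes (0 of 24 in limma, 1 adjusted over the list alone, 9 unadjusted, adjusted p = 0.0015, adjusted p = 0.382 with an estimated correlation) and adipocyte markers (1 of 4, 2 adjusted over the list alone, adjusted p = 0.00636, adjusted p = 0.344 with an estimated correlation) were higher. The called adipocyte marker was Cfd, while Plin1, Retn and Cidea were not called over all genes (limma adjusted p = 0.31, 0.15 and 0.46). Hepatocyte markers were lower (1 of 10, 1 adjusted over the list alone, median -0.21, adjusted p = 0.0107, adjusted p = 0.354 with an estimated correlation). Kupffer cell (0 of 12, 0 adjusted over the list alone, median 0.46, adjusted p = 0.00614, adjusted p = 0.437 with an estimated correlation), T and NK cell (1 of 16, 2 adjusted over the list alone, median 0.50, adjusted p = 0.00614, adjusted p = 0.382 with an estimated correlation) and pancreatic acinar markers (1 of 7, 3 higher and 1 lower adjusted over the list alone, median 0.68, adjusted p = 0.0367, adjusted p = 0.354 with an estimated correlation) were higher. The remaining 7 called lists had medians between -0.32 and 0.85. The pancreatic and xenobiotic lists were the 2 that lost their call without knockout array 1, and the pancreatic list lost it under normexp too.

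Treated knockout livers were compared with treated wild-type livers to see how far the genotypes differ under the hormone. Sult1e1 was 87.7-fold lower (log2 -6.45, SE 0.75, n = 4 per group), Lcn2 33.9-fold (log2 -5.08, SE 0.93), Cdkn1a 30.1-fold (log2 -4.91, SE 0.81) and Gadd45b 30-fold (log2 -4.91, SE 0.57). Lower levels were also measured for Cyp2b10 (log2 -4.18, SE 0.83), the growth factor binding protein Igfbp1 (log2 -3.93, SE 0.62), the nucleotide reductase Rrm2 (log2 -2.78, SE 0.34), Arntl (log2 -2.66, SE 0.53), Angptl4 (log2 -2.06, SE 0.22) and the liver transcription factor Hnf4a (log2 -1.14, SE 0.17). Gadd45a, a DNA damage gene, was 20.1-fold higher (log2 4.33, SE 0.30), Cfd 20.2-fold (log2 4.34, SE 0.88, and 3.54 and 5.33 without wild-type array 2 and knockout array 4) and Clstn3, a calsyntenin, 12.9-fold (log2 3.69, SE 0.24). Dbp was higher by 2.94 (SE 0.27), the bile acid transporter Slc51b by 2.61 (SE 0.53), Cxcl10 by 2.03 (SE 0.46), the replication factor Mcm2 by 1.84 (SE 0.32) and the steroid-binding globulin Serpina6 by 1.55 (SE 0.37). Limma called 4223 genes, 2661 higher and 1562 lower, and the count lay between 2991 and 3767 with any 1 of the 8 arrays compared left out. It was 5669 without untreated knockout array 1.

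Camera called 9 lists under dexamethasone, and none with an estimated correlation. Classic glucocorticoid-induced genes were lower (14 of 19, 18 adjusted over the list alone, adjusted p = 2.54e-14, adjusted p = 0.0885 with an estimated correlation), with Fkbp5 (log2 -3.94, SE 0.61, n = 4 per group) and Lpin1 (log2 -3.86, SE 0.39). Acute phase genes were lower (12 of 25, 12 adjusted over the list alone, adjusted p = 4.85e-07, adjusted p = 0.264 with an estimated correlation), with Saa3 (log2 -3.23, SE 0.57) and Saa1 (log2 -2.89, SE 0.63). Amino acid catabolism was lower (11 of 22, 12 adjusted over the list alone, adjusted p = 4.85e-07, adjusted p = 0.41 with an estimated correlation), with Tdo2 (log2 -2.35, SE 0.33), Aass (log2 -2.02, SE 0.22) and the methyl transferase Bhmt (log2 -1.92, SE 0.37). The urea cycle was lower (6 of 8, 6 adjusted over the list alone, adjusted p = 9.49e-06, adjusted p = 0.264 with an estimated correlation), with Slc25a15 (log2 -1.78, SE 0.22), the entry enzyme Cps1 (log2 -1.28, SE 0.22) and Arg1 (log2 -1.07, SE 0.16). Gluconeogenesis was lower (7 of 12, 7 adjusted over the list alone, adjusted p = 2.46e-05, adjusted p = 0.264 with an estimated correlation), with the rate-limiting Pck1 (log2 -1.58, SE 0.35) and its coactivator Ppargc1a (log2 -1.38, SE 0.31).

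Higher in treated knockout than in treated wild-type liver were interferon-stimulated genes (14 of 24 higher and 1 lower, against 17 and 2 adjusted over the list alone, adjusted p = 9.49e-06, adjusted p = 0.402 with an estimated correlation), with Ifit1 (log2 2.22, SE 0.33, n = 4 per group) and the ubiquitin-like Isg15 (log2 1.87, SE 0.22). Cholesterol synthesis was higher (9 of 24 and 1 lower, against 11 and 2 adjusted over the list alone, adjusted p = 0.0106, adjusted p = 0.751 with an estimated correlation), with the enzymes Mvd (log2 2.24, SE 0.44) and Hmgcs1 (log2 2.06, SE 0.49, and 1.42 without treated knockout array 1) and with Stard4 (log2 1.72, SE 0.28). Lipogenesis was higher (10 of 20, 10 adjusted over the list alone, adjusted p = 0.0223, adjusted p = 0.751 with an estimated correlation), with Srebf1 (log2 3.63, SE 0.52), the lipid droplet protein Pnpla3 (log2 2.45, SE 0.60, and 1.24 under an alternative) and the citrate lyase Acly (log2 2.04, SE 0.32). This list lost its call without untreated knockout array 1, which enters through the fit of all 16 arrays. B cell markers were higher (5 of 11, 6 adjusted over the list alone, adjusted p = 0.0126, adjusted p = 0.41 with an estimated correlation), with the adaptor Blnk (log2 3.02, SE 0.37), Igh-6 (log2 1.35, SE 0.24) and Pax5, at least 1.59-fold and not called under normexp. The circadian list was not called (adjusted p = 0.484, 5 of 18 members higher and 8 lower), while 22.2% of all genes were called by limma. Camera tests for a shift 1 way, and these members moved both ways. The missing list call therefore does not speak against a change in its members.

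Genotype changes without and with dexamethasone overlapped. Of the genes called in both, 158 were higher and 111 lower in each, where independence would give 55.2 and 12.1. Another 91 went opposite ways, for which no number under independence was computed. The shared estimate of spread per gene can raise the overlap in either direction here too. Cfd and Igh-6 were higher in both, and Nr3c1, Fkbp5, Lpin1, Angptl4 and Arg1 were lower in both. Across genes the 2 sets of changes correlated with r = 0.348 and rho = 0.376. Dexamethasone in wild type and knockout without dexamethasone share the same untreated wild-type arrays. In a simulation without any effect, this sharing alone gave a correlation of 0.497 and a covariance of 0.0474. The observed r was 0.025 and the observed covariance 0.0069. Real effects widen the spread of the changes, so the simulated and observed r are not comparable in size. With the 4 untreated wild-type arrays divided between the 2 comparisons in each of 6 ways, r lay between -0.157 and -0.012.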

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

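The tests of adipose genes and of other cell types were chosen after the result was seen, and the splits of the arrays, the interaction tests, the background and position tests of olfactory receptor genes and the tests of single arrays were set before it. Other splits of the 8 arrays of a pairwise comparison asked whether an arbitrary grouping calls as many genes. They mix the real groups, which puts any real difference into the spread and lowers their counts. Those counts are therefore no measure of false calls. An offset between slides would favour the real split as well, so the splits cannot tell treatment or genotype from slide. For dexamethasone in wild type, 1 of 35 splits, the real one, gave 2277 genes and the highest other gave 1. For dexamethasone in knockout 1 of 35 gave 677 and the highest other gave 174. For knockout without dexamethasone 1 of 35 gave 543 and the highest other gave 236, and with dexamethasone 1 of 35 gave 4223 and the highest other gave 2. For the interaction 2 of 100 splits within the genotypes gave as many as the real 867, and the highest other gave 965. That split kept the wild-type groups whole and crossed the knockout arrays, so it still held the wild-type response. Splits that cross the wild-type groups put that response into the spread, which lowers their counts. The 2 of 100 met the size set beforehand, but a crossed knockout grouping called more genes than the real one. These splits therefore do not exclude chance for the interaction count.

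Responses to dexamethasone differed between the genotypes by the limma interaction test for 16 printed genes. The differences on the log2 scale were -4.92 for Gadd45b, -4.68 for Defb1, -4.09 for Sult1e1, -3.72 for Orm3, -1.75 for Usp18, -1.46 for Aass, -1.33 for Slc25a15 and -1.10 for Cd3e. They were 0.99 for Fgfr4, 1.66 for Nr3c2, 1.66 for Stard4, 2.57 for Dbp, 2.86 for Srebf1 and 3.44 for Hspa1l, which was above background on 1 of 4 arrays in 2 groups. Fitted values of -5.67 for Tg and 4.65 for Olfr1371 rest on the floor and give no size, as each was above background on 0 of 4 arrays in 1 or 2 groups. Under normexp background correction Tg (-2.51), Olfr1371 (1.13), Hspa1l (1.51), Nr3c2 (0.95), Fgfr4, Slc25a15, Stard4 and Srebf1 lost their call. Without untreated wild-type array 2, Sult1e1 (-3.87), Orm3 (-3.45), Slc25a15 (-1.24), Srebf1 (2.59) and Stard4 (adjusted p = 0.061) lost their call, and without 13, 4, 6, 12 and 7 of the 16 arrays in turn. By camera, 10 lists differed, and none with an estimated correlation. The medians were -0.646 for classic glucocorticoid-induced genes, -0.595 for female-biased genes, -0.401 for the acute phase, -0.329 for amino acid catabolism, -0.312 for stellate cell markers and -0.263 for the urea cycle. They were 0.355 for glucocorticoid handling, 0.492 for lipogenesis, 0.632 for interferon-stimulated genes and 0.695 for cholesterol synthesis.

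In 19 of 349 groups of 4 arrays, 1 array lay far from the other 3, by the share of the group's range that separated it from its nearest neighbour, and chance alone would give about 17.4. Untreated wild-type array 4 stood apart in 5 of them, for Nr3c1 probe A_52_P138090 (0.884), Fam107a (0.846), Aass (0.864), the cholesterol synthesis list (0.859) and the T and NK cell list (0.832). Untreated knockout array 1 stood apart in 4, for Fkbp5 (0.953), Hspa1l (0.934), Olfr1471 (0.924) and Fgfr4 (0.887). Treated knockout array 1 stood apart for Nr3c1 probe A_52_P254174 (0.885), Cxcl10 (0.91) and Hmgcs1 (0.958). The others were untreated knockout array 4 for Sult1e1 (0.886) and Usp18 (0.892), treated wild-type array 2 for Usp18 (0.843) and Vcam1 (0.851), treated wild-type array 3 for Fcmr (0.835), untreated wild-type array 1 for Fgfr4 (0.911) and treated knockout array 4 for Gadd45a (0.866).

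Olfactory receptor genes were called between the treated genotypes in 138 of 412 cases (33.5%) against 21.9% of other genes (Fisher's exact test, adjusted p = 1.4e-07), and for dexamethasone in knockout in 50 (12.1%) against 3.4% (Fisher's exact test, adjusted p = 7.2e-14). For the interaction 15.5% were called against 4.3% (Fisher's exact test, adjusted p = 2.2e-17). Between the untreated genotypes 44 (10.7%) were called, 40 of them higher, against 2.7% (Fisher's exact test, adjusted p = 7.8e-14). For dexamethasone in wild type 9.2% were called against 12% of other genes (Fisher's exact test, adjusted p = 0.091). Fisher's exact test takes the genes as independent, but all were measured on the same arrays. These p values therefore do not measure replication across arrays. Between the treated genotypes, the log2 change of a spot hardly followed that of its neighbours (r = 0.069 over all 28436 spots tested), and the called olfactory spots lay 9.1 spot units from their nearest fellow against 9.4 in random sets of called spots. This argues against unevenness on the slides for that comparison, the only one in which position was tested. Signal near background remains open: the called genes had a median level of -3.40 in their brightest group, against -3.47 for those never called and a lower quartile of -2.83 for all genes. Small offsets between slides at that level may therefore account for these calls, and slide and group cannot be told apart. No biological explanation was tested.

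Cfd was at 1.13 and 1.93 in untreated and treated wild-type livers and at 7.06 and 6.27 in the knockout ones, and a single array was not the source: without any 1 of the 8 arrays compared the difference lay between 5.69 and 6.17 untreated and between 3.54 and 5.33 treated. Adipose tissue in the knockout livers is a possible explanation, since adipocytes make Cfd. The 7 other adipocyte genes had a median change of 0.33 (error 0.12) treated, under 1, the size set against adipose tissue, which argues against it as the whole source of the rise there. Untreated, the median of 0.87 (error 0.27) fell short of 2, the size set for adipose tissue, but did not lie under 1 by more than its error, so adipose tissue remains open in that comparison. Fabp4 changed by 0.17 (SE 0.30) and Lpl by 0.87 (SE 0.38) untreated, and Cidea by 1.59 (SE 1.09) untreated and -0.08 treated, while Plin1, Retn and Adig were close to background, Car3 is abundant in wild-type liver (8.28) and Adipoq was above background on 2 of 16 arrays. The knockout genotype as a direct cause is the biological explanation of the design and was not tested apart from these.

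B, T and NK cell markers fell in treated knockout liver with a median of -0.54, which was -0.32 without untreated knockout array 1, where both lists lost their call, so that array could be the source of the list calls. It was not the source for Cd79b, Fcmr, Ms4a1 and Cd3e, which kept their call without any 1 of the 8 arrays compared. Printed genes were picked mostly for calls that held, so these do not speak for the other markers. Ms4a1 and Cd79b lost their call with only the groups compared in the fit. A lower share of all cells other than hepatocytes remains open. Medians were -0.17 for endothelial, -0.33 for Kupffer, -0.05 for stellate and -0.04 for cholangiocyte markers, and the differences from the lymphocyte markers had two-sided permutation p values from 0.085 to 0.35. An effect of dexamethasone on lymphocytes that kept the receptor is the biological explanation of the design and was not tested.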

How the results depend on the processing

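The alternatives that left out untreated knockout array 1 as standing apart, or both dim arrays, were chosen after the result was seen. Slide as a block was impossible, as no slide held more than 1 group. With replicate as a block, although the numbers were not taken to pair the samples, the block fit called 2237, 819, 1076, 794 and 4245 genes, in the order dexamethasone in wild type, in knockout, interaction, knockout untreated and knockout treated. Nr3c1 kept its fall in each alternative, from -2.08 to -1.93 untreated and -2.05 to -1.87 treated with any 1 array compared left out. The counts of 2277, 677, 867, 543 and 4223 became 1233, 46, 83 (22 positive, 61 negative), 86 (46 higher, 40 lower) and 2406 under normexp, and 5127, 1857 (1041 higher, 816 lower), 2808 (1587, 1221), 1680 (1020, 660) and 6842 with array weights. A further 2-fold threshold gave 859, 448, 742, 336 and 1869, a smaller number by construction. With no filter on dim probes the knockout response, interaction and untreated genotype counts were 426, 537 and 272, and with a stricter filter, which tests fewer genes, the last pair were 576 and 360. Quantile normalization gave 1103 for the knockout response. Only the groups compared, with fewer arrays for the spread, gave 127 (58 higher, 69 lower) and 77 for the knockout response and untreated genotype. The same change raised the counts to 2824 for dexamethasone in wild type and 5382 for the treated genotype. Fewer arrays alone therefore do not account for the fall. The comparisons that fell hold the untreated knockout arrays, which had the lowest mean r with their own group (0.963 to 0.980). Without untreated knockout array 1 the counts were 3377, 941 (595 higher, 346 lower), 1526 (870, 656), 455 (232, 223) and 5669, with 525 genes shared with the 677 and 312 with the 543. Without both dim arrays they were 3459, 1093 (695, 398), 1553 (800, 753), 380 and 6120. Leaving out each array of the groups compared gave 1240 to 2265, 320 to 941, 506 to 1526, 162 to 659 and 2991 to 3767, lowest without untreated wild-type array 2 for wild-type dexamethasone, interaction and untreated genotype, and without treated knockout array 3 for knockout dexamethasone. Of the genes called in wild type, those passing the same way in knockout (181) were 28 under normexp, 105 with no filter, 441 with weights, 75 at 2-fold, 34 with only the groups compared and 100 to 207 with 1 array out. Those passing the interaction (452) were 64, 231, 1811 and 265 under the first 4 of these, 861 without untreated knockout array 1 and 203 to 861 with 1 array out. Their median knockout change (0.19) was 0.099 with weights, 0.117 without untreated knockout array 1, 0.278 at 2-fold and 0.117 to 0.223 with 1 array out. Lists called (8, 4, 10, 18 and 9) were 0 in all 5 comparisons by camera with an estimated correlation, against 4, 0, 0, 4 and 4 at an unadjusted p under 0.05. Fry called 0 for the knockout response, 0 for the interaction and 8 for the untreated genotype. Normexp called 17 for the treated genotype, and leaving out untreated knockout array 1 gave 2 for the knockout response and 6 for the interaction. Quantile normalization gave 7 for the interaction and 13 for the untreated genotype. Of 254 named-gene results, normexp lost the call of 88, no filter 41, mean of probes 22 and only the groups compared 38 of 219, and 1 reversed: Enah with dexamethasone in knockout was -0.54 with no filter, which takes another probe of the gene. Other than where fewer genes were tested, the cause was not tested. Signal over background limits the dim genes, since 57.3% to 67.9% of spots passed it.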
